A study of Mus musculus with 6 samples.

How the data were processed

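RNA was measured in prefrontal cortex samples of male C57BL/6 mice that received polystyrene nanoparticles (PS NPs) or water by oral gavage every day for 6 months. The labels name 3 samples of the control group (0 mg/kg) and 3 of the PS_high group (50 mg/kg), with mice 5 weeks old at the start and 30 weeks old at sampling. Libraries were made from total RNA with ribosomal RNA removed (Ribo-Zero) and a stranded kit, and the submitters' processing notes name HISAT2, StringTie and TopHat, whose versions are not given in the sources used here. The labels list separate samples. For single genes and isoforms, p-values rest on the spread between these samples. edgeR partly replaces this spread by a trend over features of like abundance. For circRNAs this replacement was large, and relative to the host gene it was nearly complete. Those p-values therefore rest mostly on the trend and not on the spread of the single circRNA. The p-values of gene lists rest on a preset correlation between genes unless an estimated one is named.

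The first table holds linear transcripts. Its deposited values are FPKM per isoform and a deposited estimated count per isoform, in which reads shared by several isoforms of a gene are divided between them. All deposited estimated counts were whole numbers, and isoforms with a count of 0 carried 0.0001 FPKM. The second table holds circular RNAs (circRNAs), with the deposited count of back-splice reads and a deposited signal, SRPBM, which was equal to the count scaled by 1 total per sample. The back-splice counts are reads across the junction that closes the circle. The genome build is not given in the sources used here. Of 917 small nuclear RNA genes present both in the table and in an annotation of GRCm38.p6, 792 had the same positions, and coordinates below are those of the tables.

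The linear table had 175010 isoforms, 170732 of them with a gene symbol and 33304 of them assembled rather than annotated. Gene counts were the sums of estimated counts over 155855 isoforms that share exons with a gene of the same symbol, which left out isoforms inside introns (15.0% to 19.1% of the counts of a library) and isoforms without a symbol. Genes and isoforms with a mean of at least 0.5 FPKM over the 6 libraries were tested. A gene was taken as a long non-coding RNA (lncRNA) gene from the transcript types of the table. circRNAs with back-splice reads in at least 3 of the 6 libraries were tested. Where the table gave a host gene as an Ensembl identifier, its symbol was taken from a name table (2792 of 2792 found).

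Counts were tested for PS_high against control with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), two-sided, with TMM library factors for genes and isoforms and with the library totals behind SRPBM for circRNAs. The Benjamini-Hochberg threshold was an adjusted p under 0.05. To compare a circRNA with its host gene, the host's gene count plus 1, relative to the size of the linear library, entered the edgeR model as an offset. Sums of SRPBM and numbers of circRNAs were compared with an exact two-sided permutation test, for which 3 against 3 samples allow no p below 0.1. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation. Lists with at least 5 tested genes entered, 41 of 45. Those of infiltrating leukocytes, ependymal cells, the olfactory bulb and mitochondrially encoded transcripts had fewer and were left out. Depth-scaled counts (CPM, from edgeR) are given as mean and SD over 3 samples, and log2 fold changes with the standard error (SE) derived from the edgeR F statistic. Where all libraries of a group had 0 reads, a fold is a lower bound from a floor of 3 counts over the group, which covers counting error only.

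The groups, the filters, the 45 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. That plan expected FPKM only and named limma on log2 FPKM as the test. The table proved to hold counts, so edgeR was taken as the test after that was seen, and the planned limma fits and DESeq2 1.42.0 are among the alternatives. Several ways to sum isoforms into genes were tried, and all are reported as alternatives. The host gene offset was at first the host's count plus 1 alone. It was rescaled to the libraries after its result was known, and the earlier form is also an alternative (library factors of the linear genes).

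The named genes were the 8 higher and 8 lower with the largest fold change among those past the threshold, with no overlap between the groups and at least 1 FPKM in a group, filled up by the smallest p. Predicted genes, pseudogenes and lncRNAs were taken 3 higher and 3 lower by the same rule, isoforms and circRNAs 5 and 5, and each gene list contributed up to 4 members. Further genes (Gfap, Aif1, Cldn5, Mbp, Hmox1, Fos, Bdnf, Ache, Ttr, Hba-a1 and Drd2) were fixed by name. Pseudogenes, antisense genes and genes with near-identical copies can share reads with other genes, so their values are uncertain.

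The steps were tested on simulated data with 200 changed features per run. Of genes with a 2-, 4- or 16-fold change, 7.46%, 64.2% and 98.5% were recovered among 20271 genes. In this run 1 gene list was doubled as well. Of its 131 calls on genes, 14 fell on unchanged genes, a larger share than the Benjamini-Hochberg threshold is set to allow. Of isoforms, 0% were recovered at any of these folds among 69203, and after that result a run with a low spread between samples was added, in which 26.9%, 98.5% and 100.0% were recovered. Of circRNAs, 1.54%, 4.48% and 18.2% were recovered among 3249, and relative to the host gene 0%, 7.46% and 37.9%. Alternatives were another tool, another library factor, filter, pseudocount or isoform sum, leaving out each library, and replicate number as a block. Tests of gene lists among the hosts of called circRNAs were not run, since fewer than 20 circRNAs passed. Tables were read and plotted with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.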

Results

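Linear and circular RNA of the prefrontal cortex were compared between mice given 50 mg/kg PS NPs per day by gavage for 6 months (PS_high, n = 3 samples) and mice given water (control, n = 3). The estimated counts of linear transcripts summed to 65219552, 61842978 and 66004386 in the control libraries and to 63466209, 53344395 and 61417412 in the PS_high libraries. Back-splice reads, which mark circRNAs, numbered 19494, 17554 and 19957 in control and 19880, 15658 and 17353 in PS_high. In a principal component analysis of the 2000 most variable genes, PS_high 1 stood apart on the first component (score 57.0, against -28.3 to 14.4 for the other libraries), which held 26.8% of the variance.

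The first comparison asked which genes of the prefrontal cortex differed after the PS NP exposure. Gsk3b, a kinase that phosphorylates glycogen synthase and the microtubule protein tau, rose from 93.6 ± 10.5 CPM in control to 474 ± 111 CPM in PS_high (SD, n = 3 each). Sprn, which encodes the prion-related protein Shadoo, rose from 14.2 ± 0.432 to 72.0 ± 9.45 CPM, the same 5.06-fold difference as Gsk3b. Zfp1, a zinc finger gene, fell from 57.3 ± 2.79 to 13.8 ± 1.22 CPM, and Hp1bp3, a chromatin protein that binds heterochromatin protein 1, fell from 253 ± 7.79 to 97.1 ± 5.90 CPM. Gm48239, an lncRNA gene on the strand opposite to Cadps whose reads are therefore uncertain, fell from 153 ± 32.1 to 19.1 ± 6.59 CPM.

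These 2 higher and 3 lower genes were all that passed in edgeR among 20272 genes, and in each of them all 3 PS_high samples lay on 1 side of all 3 controls. The log2 fold changes were 2.34 (SE 0.21) for Gsk3b, 2.34 (SE 0.16) for Sprn, -2.05 (SE 0.15) for Zfp1, -1.38 (SE 0.13) for Hp1bp3 and -3.0 (SE 0.28) for Gm48239. Their adjusted p were 0.0348, 0.0171, 0.0171, 0.0348 and 0.0392 in that order. Gsk3b lies on chromosome 16 (38089001 to 38246084), Sprn on chromosome 7 (140150628 to 140155149), Zfp1 on chromosome 8 (111643058 to 111671831), Hp1bp3 on chromosome 4 (138216296 to 138244683) and Gm48239 on chromosome 14 (12373797 to 12386067). In Gsk3b and Hp1bp3 the isoform with the most reads also differed between the groups, and on FPKM, which divides by isoform length, their log2 fold changes were 0.84 and -0.37 in limma. At an unadjusted p under 0.05 there were 554 genes (2.73% of those tested), and 1438 genes (7.09%) had groups that did not overlap, where chance gives 10%. With replicate number as a block 0 genes passed in edgeR, with 650 at an unadjusted p under 0.05. DESeq2 called 47 genes, all 5 among them, and limma on FPKM called 0, with 641 at an unadjusted p under 0.05. With annotated isoforms only, edgeR called 0 (694 at an unadjusted p under 0.05). There the adjusted p were 0.654 for Gsk3b, 0.333 for Sprn and 0.21 for Hp1bp3, and Zfp1 and Gm48239 were not tested. All counts of Zfp1 were those of assembled isoforms, MSTRG.39123.1 (67.1% in control, 65.0% in PS_high) and MSTRG.39123.6 (32.9% and 35.0%). For Gm48239 the assembled isoform MSTRG.11440.1 held all counts in control and 97.3% in PS_high. The calls of Zfp1 and Gm48239 thus rest wholly or mostly on assembled rather than annotated isoforms. With the isoform of highest mean only, edgeR also called 0 (568). In edgeR none of the 5 passed without control 1 (2 genes past the threshold), control 2 (0, with 507 at an unadjusted p under 0.05), control 3 (4 genes) or PS_high 2 (0, with 634). There were 17 genes without PS_high 1, which included all of the 5 but Gm48239, and 4 without PS_high 3, which included Gsk3b, Sprn and Gm48239.

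**Figure D1:**
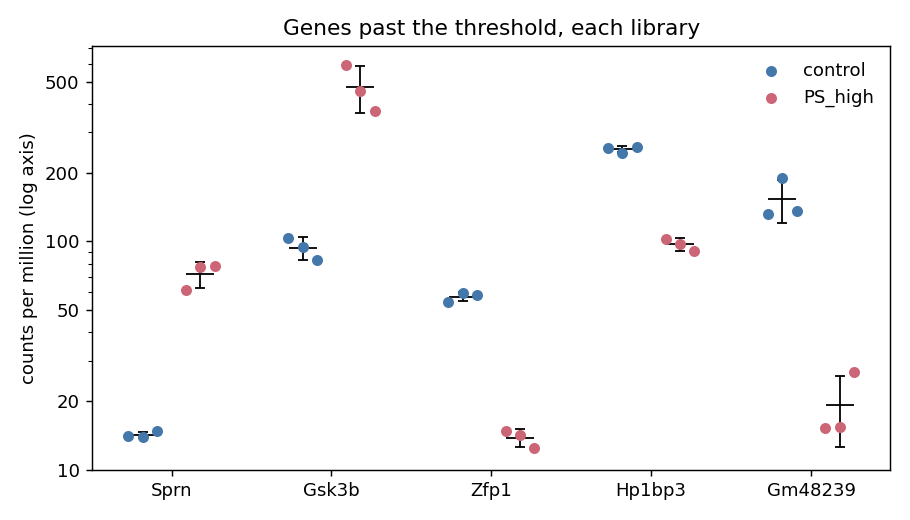
Counts per library, scaled to CPM on a log axis, of the 5 genes past the threshold in control and PS_high, with the mean and SD as black bars (n = 3 each). The PS_high points of Sprn and Gsk3b lie above, and those of Zfp1, Hp1bp3 and Gm48239 below, all 3 controls.

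The other genes named by rule did not pass. Snap25, a SNARE protein of synaptic vesicle fusion, stood at 497 ± 99.1 CPM in control and 1370 ± 268 in PS_high (adjusted p = 0.26 in edgeR), and Stx12, an endosomal syntaxin, at 46.8 ± 9.39 and 150 ± 12.1 (adjusted p = 0.0731). Creb1, an activity-regulated transcription factor, had a log2 difference of 2.00, Ube2v1, a ubiquitin-conjugating enzyme variant, of 2.80 and the deubiquitinase gene Usp49 of 2.32, each with an adjusted p of 0.0886. Nrbf2, a gene of autophagy, had a log2 difference of 1.23. On the lower side, Adarb1, which edits RNA of glutamate receptors, stood at 163 ± 20.4 and 74.6 ± 19.0 CPM (adjusted p = 0.789). The integrin activator Fermt2 (-0.79), Pyurf (-1.48), Zfp804a (-2.82), the potassium channel gene Kcnk3 (-2.15) and the angiotensin receptor gene Mas1 (-1.09) had lower log2 values that did not pass either. Among symbols of predicted genes and pseudogenes, Rpl5-ps1 (2.56), Gm24950 (0.93), Gm25177 (3.17), Gm14399 (-1.68) and Gm3696 (-1.51) did not pass, and reads shared with related genes make them uncertain. DESeq2 called each gene of this paragraph but Gm25177, and without PS_high 1 Ube2v1 (log2 3.06), Rpl5-ps1 (2.76) and Gm14399 (-1.98) passed in edgeR. The sign was kept in 22 of 23 alternatives for Creb1 (lowest -0.39), Snap25 (lowest -0.41), Adarb1 (highest 0.22) and Mas1 (highest 0.0). For Gm14399 it was kept in 21 of 23 (highest 0.16).

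The genes fixed by name as markers of injury and of transmitter systems showed no difference beyond the spread between samples (adjusted p = 1 for each in edgeR). Gfap, the astrocyte filament gene that rises in gliosis, stood at 59.7 ± 4.18 CPM in control and 72.5 ± 24.4 in PS_high (n = 3 each). The myelin gene Mbp stood at 195 ± 1.64 and 193 ± 21.1 CPM. Log2 differences were -0.28 for the microglial gene Aif1, 0.00 for the endothelial tight junction gene Cldn5, -0.47 for the haem oxygenase gene Hmox1, 0.53 for the neurotrophin gene Bdnf, -0.11 for the acetylcholinesterase gene Ache and -0.20 for the dopamine receptor gene Drd2. Simulated 2-fold changes were recovered for 7.46% of genes, so differences of that size were mostly not detectable.

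For lncRNA genes, which the series aims at as marker candidates, the same fit was read over 2071 tested genes. Gm48239 was 1 lncRNA gene that fell, 8.0-fold, and none rose. Of the best known brain lncRNAs, Meg3 had a log2 difference of 0.69 and Mirg of -0.57, and neither passed. Adjusted over the list alone the count was also 1, and 60 lncRNA genes (2.9% of those tested) had an unadjusted p under 0.05, while DESeq2 called 5 and limma on FPKM 0. With replicate number as a block it was 0, with 72 at an unadjusted p under 0.05. Gm48239 did not pass without control 1, control 2, control 3 or PS_high 2 (0 lncRNA genes in each, with 45 to 59 at an unadjusted p under 0.05) nor without PS_high 1, where 2 other lncRNA genes passed.

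The isoform comparison asked whether single transcripts differed where gene totals did not. ENSMUST00000027579, a coding isoform of Actr3, which encodes a subunit of the Arp2/3 complex that branches actin filaments, had 1, 1 and 2 counts in control and 2720, 2128 and 2717 in PS_high. ENSMUST00000203820, an isoform of the splicing regulator gene Tra2a annotated as a target of nonsense-mediated decay, had 1, 1 and 1 counts in control and 535, 433 and 373 in PS_high. ENSMUST00000167448 of Arel1, a ubiquitin ligase gene that inhibits apoptosis, had 1, 1 and 1 in control and 207, 254 and 218 in PS_high. Within Actr3 the estimated counts moved between isoforms: ENSMUST00000178474 held 78.3% of the gene's counts in control and 0.0% in PS_high, while ENSMUST00000027579 went from 0.0263% to 36.8% and the retained-intron isoform ENSMUST00000186008 from 3.66% to 51.8%. The 2 coding isoforms span nearly the same positions (125392906 to 125435547 and 125392905 to 125435727), so reads they share could be assigned to either. Even pairs of libraries within a group held 2846 ± 217 isoforms with at least 100 reads in 1 library and 0 in the other. The counts of the whole Actr3 gene were 5089, 4846 and 5272 in control and 7608, 5792 and 7149 in PS_high.

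In edgeR the 3 isoforms rose and none fell among 69330 tested (adjusted p = 0.031, 0.031 and 0.0472), and 2480 (3.58% of those tested) had an unadjusted p under 0.05. With replicate number as a block 0 isoforms passed, with 2984 at an unadjusted p under 0.05. The fitted log2 fold changes of 10.89 (SE 0.44), 8.76 (SE 0.36) and 7.80 (SE 0.37) depend on the prior count, because control counts were near 0. Isoforms that did not pass included ENSMUST00000114657 of Fmr1, the fragile X gene, with 3421, 2794 and 4142 counts in control and 0 in PS_high (at least 3187.0-fold lower over the group, adjusted p = 0.159), and ENSMUST00000039074 of the synaptic scaffold gene Shank3 (at least 1657.0-fold lower). ENSMUST00000178474 of Actr3 (at least 3662.4-fold lower, adjusted p = 0.156), ENSMUST00000186008 of Actr3 (log2 4.39), ENSMUST00000100986 of Esyt2 (9.71), MSTRG.23778.1 of Dido1 (-7.05) and MSTRG.9210.5 of Unc79 (-9.32) did not pass either. DESeq2 called 978 isoforms, among them the 7 named here as not passing, and limma on FPKM 22, among them those of Actr3, Fmr1, Shank3 and Esyt2 in this paragraph. None of the 3 passed when any library was left out in edgeR: without control 1, control 2, control 3, PS_high 2 or PS_high 3 there were 0 isoforms (2221 to 2753 at an unadjusted p under 0.05), and without PS_high 1 there was 1. The log2 value of ENSMUST00000027579 stayed at 10.74 to 11.25 in these fits. With quality weights 0 isoforms passed (2085 at an unadjusted p under 0.05). With no filter 0 passed as well (3878), with adjusted p of 0.0717, 0.0717 and 0.144 for the 3 in edgeR.

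**Figure D2:**
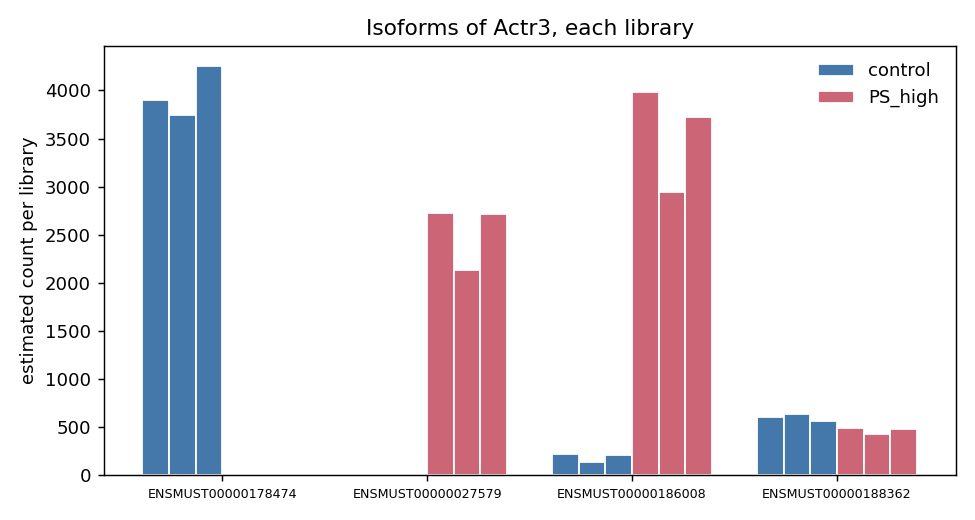
Estimated counts of 4 Actr3 isoforms in each library, 1 bar per library, in the order control 1 to 3 and PS_high 1 to 3. ENSMUST00000178474 lies between 3745 and 4251 in control and at 0 in PS_high, where ENSMUST00000027579 lies between 2128 and 2720.

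Gene lists for cell types and functions were tested to see which groups of genes moved together, and 3 of 41 passed in camera with a preset correlation. With an estimated correlation 0 passed: p = 0.159 (adjusted p = 1) for the meningeal and perivascular fibroblast list, p = 0.277 (adjusted p = 1) for the immediate early genes and p = 0.0152 (adjusted p = 0.623) for the amyloid list, with 1 list at an unadjusted p under 0.05. Genes of meningeal and perivascular fibroblasts were higher in PS_high, with 13 of 13 members above 0, a median log2 difference of 0.40 and, for example, Slc13a4 at 0.81, Ptgds at 0.42, Lum at 0.63 and Mgp at 0.59. Immediate early genes, which neurons induce upon activity, were lower with the preset correlation (adjusted p = 1 with an estimated correlation), with 16 of 17 members below 0, a median of -0.23, Arc at 44.9 ± 21.5 CPM in control and 17.9 ± 8.12 in PS_high (n = 3 each), Fos at 11.5 ± 4.38 and 8.24 ± 3.56, and Npas4 and Egr2 at log2 -0.94 and -1.23. The lowest score of the immediate early genes was that of a control library, control 2 (-0.612). In neither list did any member pass on its own. The list of amyloid precursor protein, tau and synuclein was higher, with 10 of 16 members above 0 and a median of 0.21. Its scores overlapped between the groups, with PS_high 3 (-0.073) below control 3 (0.086). Its mean log2 difference of 0.26 included Gsk3b at 2.34. Gsk3b was the member that rose, also when adjusted over the list alone, and App (0.29), Cdk5 (-0.24) and Ide (0.33) did not pass.

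With the preset correlation the adjusted p of these lists were 6.27e-04, 0.00563 and 0.00301. In limma on log2 FPKM, the test first planned, the fibroblast list passed (0.022), while the immediate early genes (0.0791) and the amyloid list (0.228) did not. With quality weights the same 2 lists lost their calls (0.0706 each), with replicate number as a block the immediate early genes (0.0545), and on ranks the amyloid list (0.152). The fibroblast list lost its call without control 1 (adjusted p = 0.317) and without PS_high 3 (0.383), the amyloid list without control 1 (0.144), and the immediate early genes without control 1 (0.17), control 3 (0.513), PS_high 1 (0.15) and PS_high 3 (0.211), and leaving out control 1 left 0 lists (6 at an unadjusted p under 0.05) and leaving out control 2 left 6. Over all 24 alternatives the adjusted p ranged from 3.44e-06 to 1 for the fibroblast list, from 2.57e-10 to 1 for the immediate early genes and from 0.00171 to 0.82 for the amyloid list.

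Markers of tissue next to the cortex and of blood moved in the same libraries as these lists. The choroid plexus list (median 0.76, 8 of 10 members above 0, adjusted p = 0.0542) held Ttr at 9.42, 427.97 and 201.54 CPM in control and 17.58, 798.96 and 502.58 in PS_high, with Sostdc1 and Kcne2 at log2 0.84 and 0.71. The fibroblast list scored lowest in control 1 (-0.809) and PS_high 1 (-0.292), the 2 libraries with the lowest choroid plexus scores (-2.123 and -1.348). The blood list (median -0.47, 6 of 7 members below 0, adjusted p = 0.109) held the haemoglobin genes Hba-a1 (-0.43), Hbb-bs (-0.80) and Hbb-bt (-0.82). Its highest score was in control 3 (0.723), where the immediate early genes also scored highest (0.618), and its lowest in PS_high 1 (-0.68), which had the second lowest score of the immediate early genes (-0.421). The choroid plexus list passed as higher in 9 of 23 alternatives, among them ranks (adjusted p = 0.0323), replicate number as a block (4.56e-10), without control 2 (9.21e-05) and without PS_high 1 (3.44e-06), over a range of 4.56e-10 to 1. With an estimated correlation it had p = 0.382 (adjusted p = 1). The blood list passed as lower in 3 of 24, without control 2 (adjusted p = 0.00341), without PS_high 2 (1.84e-04) and with no filter (0.00677), over a range of 1.84e-04 to 1, and had p = 0.19 with an estimated correlation.

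**Figure D3:**
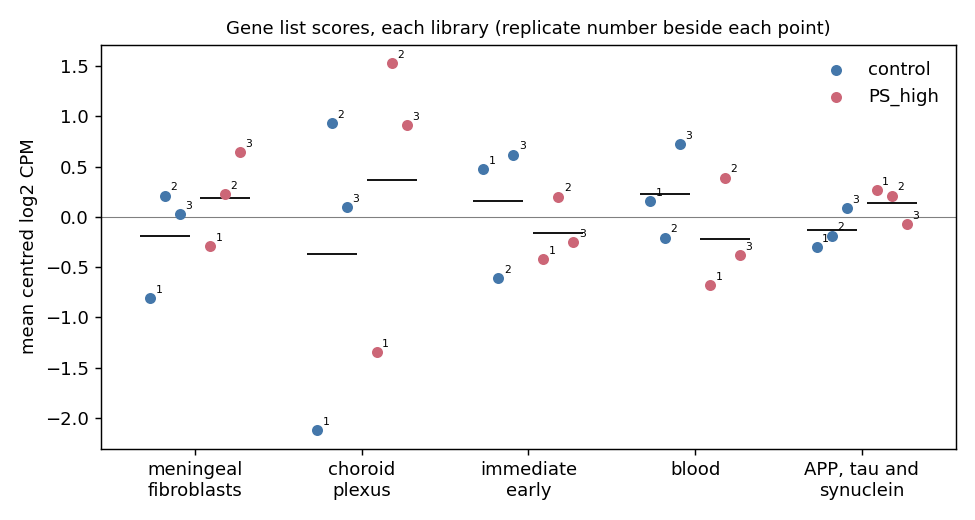
Score of 5 gene lists in each library, the mean over members of log2 CPM centred on the 6 libraries, with the group mean as a black line and the replicate number beside each point. The choroid plexus list ranges from -2.123 to 1.53, wider than the immediate early genes (-0.612 to 0.618).

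Lists of injury, inflammation and stress did not pass. Disease-associated microglia genes had 10 of 16 members above 0 (median 0.16, adjusted p = 0.186, with 0.026 without control 2 and 0.026 to 1 over the alternatives), with Spp1 at 0.54 and Cd9 at 0.40, and reactive astrocyte genes 8 of 12 (median 0.13, adjusted p = 0.534). Genes of the oxidative stress response stood near 0 (median 0.01, mean -0.03, adjusted p = 0.924), with Srxn1 at 0.66. Gclm of the same list stood at -1.26, but at -0.43 without control 3 and at 0.19 in limma on FPKM. Cytokines and inflammatory signalling (median 0.09, 8 of 22 members tested), complement and antigen presentation (0.13, 12 of 16), interferon response (-0.12, 12 of 20), xenobiotic metabolism (0.03, 12 of 16), lysosome and autophagy (0.02, 19 of 19) and apoptosis and p53 targets (-0.02, 18 of 19) had no member that passed. Members below the expression filter were not tested, so the inflammatory lists were covered only in part. Tight junctions and blood-brain barrier transporters had 8 of 15 members below 0 (adjusted p = 0.607), with Abcb1a at -0.27 and Slc2a1 at -0.28.

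Lists of neurons, glia and synapses did not pass either. Excitatory neuron markers had a median of 0.05, with Camk2a at 0.49, and GABAergic interneuron markers 0.02. Oligodendrocyte and myelin genes had 11 of 17 members below 0 (median -0.08), with Fa2h at -0.35, and microglial genes 10 of 17 (median -0.02), with Siglech at 0.53 and Fcrls at -0.23. Synaptic vesicle and presynaptic proteins had 12 of 19 members above 0 (median 0.04, adjusted p = 0.559), and Snap25 passed when adjusted over the list alone but not over all genes. Postsynaptic density scaffolds had a median of 0.04 and a mean of -0.03, with Shank3 at -0.65. Shank3 kept its sign in 17 of 23 alternatives (-0.85 to 0.33). Cholinergic, dopaminergic and serotonergic signalling had a median of -0.12, with Maob at 0.33 and Htr2a at -0.33.

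The circRNA comparison asked which circRNAs could mark the exposure. circRNA4050, a 2-exon circRNA of Ptms, the gene of the acidic nuclear protein parathymosin, had 12, 20 and 19 back-splice reads in control and 0, 0 and 0 in PS_high, at least 14.8-fold lower over the group. Its signal fell from 134 ± 38.3 SRPBM to 0 (SD, n = 3 each), while linear Ptms had a log2 difference of 0.13 (adjusted p = 1). The most abundant circRNA, mmu_circ_0001878, which by its position is Cdr1as, the circRNA that binds microRNA miR-7 in neurons, stood at 2840 ± 1090 SRPBM in control and 1630 ± 165 in PS_high and did not pass (log2 -0.80, SE 0.25, adjusted p = 0.826). It passed without control 2 (log2 -1.08, adjusted p = 0.00265) and with a median circRNA factor (-0.93, 0.0374), over a range of 0.00265 to 1. circRNAs of Strbp, Tulp4 and Slc8a1 came next in abundance and also did not pass: circRNA4811 of Strbp stood at 1710 ± 314 and 1750 ± 72.2 SRPBM, and circRNA4139 of Tulp4 at 1390 ± 157 and 1650 ± 246.

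Of 3275 circRNAs tested in edgeR, circRNA4050 (chromosome 6, 124914409 to 124914710) was 1 that fell (adjusted p = 0.00148) and none rose, with 162 (4.95%) at an unadjusted p under 0.05. Its fitted log2 value of -7.01 depends on the prior count and was -4.11 in limma with the first pseudocount. DESeq2 also called 1 circRNA, the same one, and limma on SRPBM called 0, with 196 at an unadjusted p under 0.05. The call was lost without control 1 (adjusted p = 0.946) and without PS_high 2 (0.168), where 0 circRNAs passed with 98 at an unadjusted p under 0.05, and without control 2 or control 3 there were 3 and 2. Over 17 alternatives the adjusted p of circRNA4050 ranged from 3.78e-05 to 0.946. circRNAs that did not pass included circRNA4544 of the lncRNA gene Snhg11, whose log2 value of 2.00 was 9.55 without control 1 (adjusted p = 0.0312) and 1.43 without control 2 (0.0129), over a range of adjusted p from 1.09e-13 to 1. Others were circRNA4805 (5, 7 and 8 reads in control, 0 in PS_high, at least 5.8-fold lower), which overlaps the Cdr1as position, mmu_circ_0001828 of Rasa2 (at least 4.6-fold lower) and mmu_circ_0003520 of Trim37 (6, 8 and 7 reads in control and 0, 1 and 0 in PS_high). A tested circRNA had a median of 11 reads over the 6 libraries, so most changes in single circRNAs were not detectable at this depth. The median over circRNAs lay at 0.153 with library totals as deposited and at 0.007 with factors from the circRNAs themselves, a shift that applies to every circRNA value here.

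**Figure D4:**
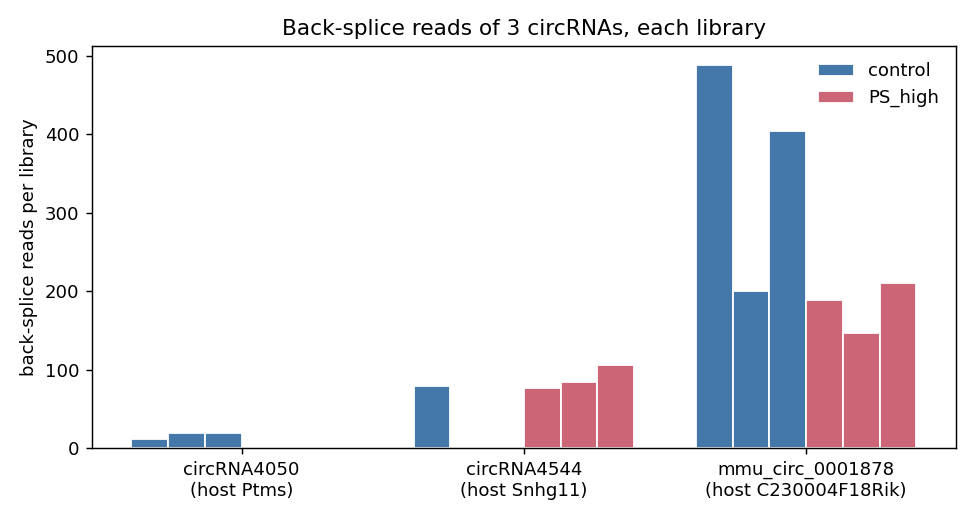
Back-splice reads of 3 circRNAs in each library, 1 bar per library, in the order control 1 to 3 and PS_high 1 to 3. circRNA4050 has 12 to 20 reads in control and 0 in PS_high, and circRNA4544 has 79 reads in control 1 and 0 in the other controls.

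Total circRNA signal did not differ beyond the spread between samples, at 149121 ± 9970 SRPBM in control and 158841 ± 15100 in PS_high (SD, n = 3 each, exact permutation p = 0.5). The difference of 9720 SRPBM was 1294 without PS_high 1, 5454 without control 2, 15202 without control 3 and 15930 without PS_high 3. The number of circRNAs detected was 5305 ± 185 in control and 4925 ± 256 in PS_high (n = 3 each, exact permutation p = 0.2). This number depends on the depth of each library. The library totals behind SRPBM were 132894000, 124860150 and 124664700 in control and 113152950, 101405400 and 118514850 in PS_high. All 3 PS_high totals thus lay below all 3 control totals. The lower number detected in PS_high therefore cannot be told apart from lower depth. The difference of -380 circRNAs was -250 without PS_high 2. The smallest p this design can give is 0.1.

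Relative to the host gene, 2 of 3130 circRNAs passed in edgeR. circRNA4050 fell relative to linear Ptms (adjusted p = 7.48e-06) and kept the call without each of the 6 libraries in turn, while its fitted log2 value of -7.07 depends on the prior count, since PS_high had 0 reads. Its call was lost in limma on SRPBM with a pseudocount of 1 (adjusted p = 0.404) or 10 times smaller than the first (0.369). Over 15 alternatives its adjusted p ranged from 2.14e-06 to 0.404. circRNA4544 of Snhg11, a neuronal lncRNA, passed as higher, but its groups overlapped, with 198 ± 343 SRPBM in control and 804 ± 111 in PS_high (n = 3 each, log2 2.02, SE 0.36, adjusted p = 2.86e-05). Its reads were 79, 0 and 0 in control and 77, 85 and 106 in PS_high, so control 1 was as high as the exposed samples. Without control 1 the fitted log2 value was 9.59, against controls at 0. The small adjusted p rests on the trend over circRNAs and not on the spread of these reads. The call of circRNA4544 was lost without control 2 (adjusted p = 0.412), without control 3 (0.107), and with no mean-variance trend in the dispersion (0.936), and limma on log2 SRPBM did not call it. Over 15 alternatives its adjusted p ranged from 1.28e-28 to 0.936. There were 4 circRNAs past the threshold without PS_high 1 and 1 without control 2. Others that did not pass were mmu_circ_0001878 (-0.93 relative to C230004F18Rik, the host the table gives for the circRNA named above as Cdr1as), mmu_circ_0001222 of Zdhhc21 (1.24), circRNA1775 of Zfp532 (1.08), mmu_circ_0001548 of Rtn2 (3.14), mmu_circ_0000425 of Esyt2 (-1.75, with 19, 13 and 29 reads in control and 0, 21 and 0 in PS_high), and circRNA4805 and mmu_circ_0001828, which had 0 reads in PS_high, and 163 had an unadjusted p under 0.05. These 163 were 5.21% of the circRNAs tested relative to the host. The values above 0 of mmu_circ_0001222 and circRNA1775 went with lower hosts, at log2 -1.45 for linear Zdhhc21 and -0.7 for linear Zfp532, neither past the threshold. The circRNAs themselves stood at 282 SRPBM in control and 202 in PS_high, and at 305 and 327. mmu_circ_0000425 passed without PS_high 2 (fitted log2 -7.64, adjusted p = 1.72e-07, over a range of 1.72e-07 to 0.999).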

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

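The limma fit on log2 FPKM or SRPBM with the first pseudocount was the test planned before the data were examined and became an alternative afterwards. The fits with DESeq2, its size factors, the sums over all transcripts of a symbol or over a locus, and circRNA read totals with TMM factors were chosen after seeing the data. The number of genes past the threshold was 5 and stayed near it with quality weights (5), an FPKM minimum of 2 (4), no library factor (4), DESeq2 size factors (5), all transcripts of a symbol (5) and locus sums (7). It was 2 with no mean-variance trend, 2 with no filter, 47 in DESeq2 (27 higher, 20 lower), 0 with the isoform of highest mean, 0 with annotated isoforms and 233 at an unadjusted p under 0.05 with a 2-fold change. limma on FPKM gave 0, and 1 with a pseudocount of 0.1, 0 as deposited, 0 with quantile normalization and 2 rescaled to TPM, where the median of all genes lay at -0.119 (-0.007 in edgeR). Leaving out 1 library gave 0 (without control 2 or PS_high 2) to 17 genes (without PS_high 1). For lncRNA genes these settings gave 0 with no trend, no filter, an FPKM minimum of 2, no library factor, limma on FPKM other than TPM, the top isoform and annotated isoforms, 5 in DESeq2, 26 at an unadjusted p with a 2-fold change, and 0 to 2 without 1 library. For isoforms they gave 0 with quality weights or no filter, 22 in limma, 23 with a pseudocount of 0.1, 20 as deposited, 21 with quantile normalization, 27 as TPM, 978 in DESeq2, 2040 at an unadjusted p with a 2-fold change, and 0 to 1 without 1 library. The 3 gene lists became 0 with an estimated correlation, 0 with the rotation test fry, 5 with no filter, 1 with an FPKM minimum of 2, 1 in each limma fit on FPKM but TPM (2), 1 with the top isoform, and 0 (without control 1) to 6 (without control 2). For circRNAs the count was 0 in limma on SRPBM with any of 3 pseudocounts, 4 with reads in at least 1 library, 0 with reads in all 6, 2 with a median circRNA factor, 159 at an unadjusted p with a 2-fold change, and 0 to 3 without 1 library. Relative to the host gene it was 1 with no trend, 8 with quality weights, 1 in limma, 0 and 0 with smaller pseudocounts, 0 with reads in all 6 libraries, 161 at an unadjusted p with a 2-fold change, and 1 to 4 without 1 library. Where a count was 0, an unadjusted p under 0.05 was met by 507 to 694 genes, 22 to 187 lncRNA genes, 2085 to 3878 isoforms, 1 to 6 lists, 32 to 196 circRNAs and 29 to 213 circRNAs relative to the host. The difference in total circRNA signal ran from 1294 to 15930 SRPBM and that in circRNAs detected from -506 to -250 without 1 library, and both kept their sign. With replicate number as a block, which the design does not name as a pairing, there were 0 genes (650 at an unadjusted p under 0.05), 0 lncRNA genes, 0 isoforms, 3 lists, 3 circRNAs and 4 circRNAs relative to the host. Of these 3 lists, 2 were shared with the main fit. The immediate early genes lost their call (adjusted p = 0.0545 in camera) and the choroid plexus list passed as higher (4.56e-10). Deviations from the group mean of samples with the same number correlated at 0.155, 0.089 and 0.06 over genes. Samples with different numbers correlated lower there, at -0.1 to 0.025. Over circRNAs the same-number values were -0.021, -0.073 and 0.055, against -0.075 to 0.099 for different numbers. The numbers were not taken to pair samples, since the labels name no pairing. A factor shared by samples of the same number is not excluded. Of the alternatives for 147 named features, 2974 left the call as it was, 67 brought a feature past the threshold, 111 took 1 below it, and 0 turned the direction of a called value, while features that never passed had no direction to keep. Counts with fewer features tested or fewer samples change by construction, and for the other differences the cause was not tested. Tested circRNAs had a median of 11 reads over 6 libraries, a depth that limits calls on single circRNAs.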

Other observations

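The tests of a switch in the leading isoform, of blood, choroid plexus, oligodendrocyte and postsynaptic covariates, and of the other splits for lncRNA genes were chosen after the results they concern had been seen. Further gene lists describe the tissue without a member that passed in edgeR. Astrocyte markers had a median log2 difference of 0.04, oligodendrocyte precursors of 0.05 with Tnr at 0.67, mural cells of 0.07 and endothelial cells of 0.00 (mean -0.01). Tnr kept its sign in 20 of 23 alternatives (-0.45 to 0.84). Markers of neighbouring regions had medians of -0.06 for the hippocampus (mean -0.09, tested as higher) and 0.29 for the thalamus and hypothalamus. Striatal neuron markers had a median of -0.10 and scored low in control 1 (-0.349) and PS_high 1 (-1.374), against 0.233 to 0.634 in the other libraries, the same 2 libraries that scored lowest in the fibroblast and choroid plexus lists. Their list tested as lower without PS_high 3 (adjusted p = 0.00323) and as higher, not passing, without PS_high 1 (0.129), with a range of 0.00323 to 1 over the alternatives. Neurotrophins and activity-regulated secreted factors had a median of 0.07, with Nptx2 at -0.59 and Nptx1 at 0.49, GABA receptors and transporters 0.01 (mean -0.02), glutamate receptors -0.02 (mean 0.00, tested as higher) and nuclear long non-coding RNAs -0.03. Medians were 0.04 for ribosomal proteins, -0.04 for oxidative phosphorylation, -0.11 for cholesterol biosynthesis (14 of 18 members below 0), 0.02 for heat shock proteins, 0.04 for the unfolded protein response (mean -0.02), -0.01 for the circadian clock (tested as higher), 0.19 for histones and 0.00 for glucocorticoid-responsive genes (mean -0.14), with Errfi1 at -1.77. Adjusted p of these lists ran from 0.559 to 1. Errfi1 ran from -2.26 to -1.13 without 1 library, and control 1 (6.35 CPM) lay below all PS_high samples (8.54, 8.71 and 11.97 CPM).

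The circRNAs of this tissue came from 4596 host genes. Dgki, a lipid kinase gene, and Nbea, a gene of synaptic membrane traffic, gave 60 circRNAs each. The circRNAs of Dgki summed to 1210 ± 65.9 SRPBM in control and 1270 ± 350 in PS_high, and those of Nbea to 472 ± 74.4 and 490 ± 109 (SD, n = 3 each). Lrp1b gave 45 circRNAs and Usp34 44, whereas 1836 host genes gave 1. Exonic circRNAs held 89.9 ± 0.0676% of back-splice reads in control and 90.7 ± 0.619% in PS_high (n = 3 each, exact permutation p = 0.1, the smallest this design can give), and intronic circles 5.03% and 4.71% (exact permutation p = 0.4).

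Splits of the 6 samples into other groups of 3 number 10 with the real one, too few for a share under 0.05. The real split gave 5 genes and the highest other 5, with 3 of 10 splits at least as high. For lncRNA genes the values were 1 and 1 (2 of 10), for isoforms 3 and 2 (1 of 10), for circRNAs 1 and 4 (6 of 10), for circRNAs relative to the host gene 2 and 3 (5 of 10) and for gene lists 3 and 12 (8 of 10). At an unadjusted p under 0.05 the real split had 554 genes, and the other splits that part control 1 from PS_high 1 had 505 to 776. The 4 splits that put control 1 and PS_high 1 together had 1395, 1435, 1009 and 1187 genes, and the split with 12 gene lists is 1 of them, which points to a structure of the samples that sets control 1 and PS_high 1 apart from the rest.

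A switch of the leading isoform between the groups was seen in 2 of the 5 genes past the threshold, which argues against it as the source of all 5 calls. In Gsk3b, ENSMUST00000114750 went from 42.0% of the gene's counts in control to 0.402% in PS_high and ENSMUST00000023507 from 29.4% to 81.2%, and in Hp1bp3, ENSMUST00000030541 went from 73.6% to 0.126% and ENSMUST00000148681 from 0.609% to 33.8%. Such switches were seen in 19.1% of 12887 genes with several isoforms, and Gsk3b and Hp1bp3 were singled out after their isoforms were seen. The leading isoform of Gsk3b went from 1750 to 8303 bases and that of Hp1bp3 from 3311 to 913, the direction of each gene's change in counts. On FPKM, which divides by isoform length, neither passed in any limma fit, and most of their log2 difference in counts was absent. This goes with a part of the switch in these 2 calls. On FPKM in limma the log2 fold changes were 0.84 for Gsk3b, -0.37 for Hp1bp3, 1.90 for Sprn, -1.30 for Zfp1 and -2.31 for Gm48239. With a pseudocount of 0.1 they were 0.87, -0.37, 2.18, -1.93 and -2.86 in that order. The values of Sprn, Zfp1 and Gm48239 thus depended on the pseudocount, and those of Gsk3b and Hp1bp3 hardly did. An effect of PS NPs on these genes stays open and was not tested apart from the group comparison.

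Isoforms read in all libraries of 1 group and in none of the other, such as ENSMUST00000178474 of Actr3, numbered 60 in the real split and up to 84 in the others (9 of 10 splits at least as high). If assignment of a gene's reads to one or another isoform varies between libraries, pairs of libraries across the groups should hold no more isoforms with at least 100 reads in 1 library and 0 in the other than pairs within a group. Pairs across the groups held 2847 ± 138 (SD, n = 9 pairs) and pairs within the groups 2846 ± 217 (n = 6 pairs), a difference of 0.778. Only a difference above the SD of 217 was set to count against the explanation. The 60 isoforms of the real split make up only 60 of those in each pair across the groups. They could not bring such a difference, so this count does not decide. A response of single isoforms, such as those of Actr3 or Fmr1, to PS NPs stays open, since the pairs were counted over all isoforms and not for these genes.

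The lower immediate early genes and the higher fibroblast genes may both reflect what tissue and blood the samples held. With the mean level of 4 haemoglobin genes as a covariate, the immediate early genes had an adjusted p of 0.991 and their median went from -0.23 (quartiles -0.55 and -0.08) to 0.06 (-0.04 and 0.10), but the call also ended with a covariate from oligodendrocyte genes (adjusted p = 0.447, median -0.05), postsynaptic density genes (0.112, -0.09) or choroid plexus genes (0.0939, -0.19), so blood content of the libraries and an effect of PS NPs on neuronal activity cannot be told apart. Over 6 samples their score had a Pearson r of 0.88 with the haemoglobin score (exact permutation p = 0.0361, r 0.82 without the 2 farthest samples, Spearman rho 0.77, exact permutation p = 0.103, adjusted p = 0.607 over 41 relations), and r was also 0.85 with the oligodendrocyte list (exact permutation p = 0.0389) and 0.84 with the postsynaptic density list (exact permutation p = 0.0611). With the choroid plexus score as a covariate, the fibroblast list had an adjusted p of 0.0571 and a median that went from 0.40 (quartiles 0.22 and 0.59) to 0.35 (0.14 and 0.46), a shift within its spread, so tissue at the edge of the dissection and an effect of PS NPs on the meninges cannot be told apart with 3 samples per group. With the other covariates the fibroblast list had an adjusted p of 0.00914 (haemoglobin), 0.00387 (oligodendrocyte) and 0.012 (postsynaptic density).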
